A study of Homo sapiens with 96 samples.

How the data were processed

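The data are ATAC-seq peak lists from HL-60 cells, a human promyelocytic leukaemia line that can be driven into several myeloid cell types in culture. ATAC-seq uses a transposase to insert sequencing adapters into open chromatin, so that a peak marks a stretch of DNA that was accessible in many of the cells of a library. Per the labels' protocols, macrophages were obtained with the phorbol ester PMA, neutrophils with all-trans retinoic acid and DMSO, and monocytes with vitamin D3. Monocyte-derived macrophages received vitamin D3 for 120 h and then PMA, and were sampled at 123 to 168 h. Some cells received 100 ng/ml lipopolysaccharide (LPS), a bacterial cell wall component, shortly before collection. Per the labels there were 96 libraries in 32 groups, with 3 replicates in each. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, part of which may be technical.

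The deposited files hold 1 peak list per library, with the chromosome, start and end of each peak in the hg38 build and no score, height or fold. Peaks were therefore called per library and not on pooled replicates. Per the submitters' processing notes, Bowtie, HOMER, SAMtools 0.1.18 and bedtools were used with hg38, and the notes as given here do not state the role of each. Read depth is unknown, because no read totals were used here, and the precision of a peak's presence in a library cannot be given as an interval. The length of each list stood in for depth. Lists held 615 to 117188 peaks, with a median of 26136. Each list was a mixture of peaks of at least 500 bp and short peaks of a single width that differed between libraries; 99.9% of the 961359 short peaks had their library's width. Within 1 kb of a gene end lay 13.8% of short peaks and 34.8% of wide peaks. No pair of lists was identical, and no list held overlapping peaks.

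Peaks on chromosomes 1 to 22 and X were merged across libraries by an overlap of 1 bp, which gave 415122 regions. A region counted as detected in a library when a peak of that library lay in it. Region tests used the 92 libraries with at least 3000 peaks and the 58154 regions detected in at least 10 of them. Detection (1 or 0) was fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 32 groups and a natural spline with 3 df of log10 peak number. Moderated tests of 12 comparisons shared the estimate of spread from all groups, and Benjamini-Hochberg adjusted p under 0.05 was called. Comparisons between macrophages, neutrophils and monocytes averaged over the time points present on both sides. Monocyte-derived and direct macrophages were matched by time after PMA, and LPS by condition. The other comparisons averaged all groups of each side; monocyte-derived macrophages and late monocytes share no time point. The reported difference is a difference in the fraction of libraries with a peak after the adjustment for list length, with its SE; as a linear estimate it can lie slightly beyond 1 or below -1. Counts of libraries with a peak are given beside it, unadjusted. The moderated tests treat a value of 1 or 0 as normally distributed. The size of very small p-values depends on that model and is no exact measure of the evidence. "Late" means 48, 96 and 120 h and "early" 3, 6 and 12 h.

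Shares of peaks were tested per library, in libraries with at least 1000 peaks, by two-sided permutation tests of the share after removal of the same spline. They were exact where at most 100000 assignments existed and used 100000 resamples otherwise, with 1e-05 as the smallest possible p. A peak or region was assigned to the protein-coding gene whose span held its midpoint, or else to the gene with the nearest end within 50 kb. The gene table (RefSeq, GRCh38.p14, 19974 protein-coding genes) carries no strand, exons or untranslated regions, so "gene end" stands for either end of a gene and not for its transcription start. The design planned the distance from the start. As a check of the build, 13.7% of regions seen in 5 or more libraries lay within 1 kb of a gene end, against 3.78% after a shift of 5000 bp.

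The tests, the alternatives and 18 gene lists were fixed before the data were examined. The lists were neutrophil granule genes, mature neutrophil genes, monocyte markers, macrophage markers, AP-1 and immediate-early genes, vitamin D targets, retinoic acid targets, LPS and NF-kB response genes, interferon response genes, progenitor and leukaemia genes, myeloid transcription factors, cell cycle genes, adhesion and cytoskeleton genes, T and NK cell markers, B cell markers, erythroid and megakaryocyte markers, housekeeping genes, and a list of 2 genes whose results, among them 1 of the 40 called shares, are not given here. Nearly all symbols matched the gene table; 33 of 34 interferon genes and 35 of 36 myeloid transcription factors did. Shares of all lists over the 12 comparisons made 216 tests, adjusted together.

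Named regions followed a rule fixed in advance. In each comparison they were the 6 called regions per direction with the largest absolute difference and a gene within 50 kb, 1 region per gene, and up to 8 list genes per direction with the smallest adjusted p. Where fewer than 5 regions were called, the 5 list genes with the smallest p were to be named, and CDKN2A was named as a check of the line. The text names a part of the 291 regions this gave. Similarity of replicates was the correlation of depth-adjusted detection between libraries. It was tested one-sided by permuting labels within lineage or within time point; the side was not fixed in advance. Peak numbers were compared on the log10 scale with the same permutation scheme.

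The fit was tested on simulated data before use. With 6000 of the regions changed by 4 on the log-odds scale, it recovered 61.9% of them for macrophage against neutrophil, 77.9% for macrophage against monocyte and 62.2% for neutrophil against monocyte. The share was 42.1% for monocyte-derived macrophage against monocyte and 59.3% against macrophage. It was 23.4%, 12.1% and 21.5% for macrophage, neutrophil and monocyte against undifferentiated cells, 20.2%, 8.05% and 34.8% for late against early macrophages, neutrophils and monocytes, and 65.1% for LPS. Among the calls in these simulations, unchanged regions made up 15.4%, 3.97%, 10.1%, 15.0%, 13.8%, 20.2%, 32.6%, 19.6%, 6.84%, 4.73%, 7.32% and 8.39% in the same order, in most comparisons above the share that the threshold of 0.05 allows. As many regions were raised as lowered, but of the recovered ones 64.5%, 51.4%, 38.0%, 33.9%, 33.6%, 48.1%, 28.6%, 47.9%, 53.1%, 50.1%, 41.7% and 56.7% were higher, in the same order. The method thus recovers one direction better than the other in several comparisons. This simulation was added after a first one with 300 changed regions, of which 12 to 124 were recovered per comparison. There, unchanged regions made up 76.34%, 86.81% and 76.69% of the calls for macrophages, neutrophils and monocytes against undifferentiated cells, and 3.125% to 41.23% in the other comparisons. Apart from the changed regions, both simulations drew detection independently from a term per region and per library. They held no structure shared by groups, replicates or short peaks, so unchanged regions may make up more of the calls in the real data. For shares, a list raised by 3 SD was recovered at an unadjusted permutation p under 0.05 in 12 of 12 comparisons. Of 216 tests without an effect, 14 had an unadjusted p under 0.05 and 0 passed the adjustment.

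Alternatives comprised other minimum list lengths, a stricter region filter, no adjustment for list length, a 50% overlap rule, a replicate block, other gene distances and leaving out each replicate number. Added after the lists were seen were peaks of at least 500 bp only, the percentage of short peaks as a second covariate, leaving out 8 libraries with over 50% short peaks, detection minus the expectation of a logistic model with a term per region and per library, and the LPS comparison without monocyte-derived macrophages. Planned filters on peak scores could not be applied, since the lists carry none, and motif shares were not computed because no genome sequence was used. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, patsy 1.0.2 and matplotlib 3.10.9 were used. LPS libraries entered only the LPS comparison, and 4 libraries under 3000 peaks entered no region test except in the alternative without a minimum.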

Results

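Open chromatin was profiled in undifferentiated HL-60 cells and along their differentiation into macrophages, neutrophils and monocytes at 3, 6, 12, 24, 48, 96 and 120 h. Monocytes turned into macrophages with PMA were profiled at 123, 126, 132, 144 and 168 h, which is 3 to 48 h after the switch. LPS-treated cells were added for macrophages at 48 and 120 h, neutrophils and monocytes at 120 h, and monocyte-derived macrophages at 168 h. Each of the 32 groups had 3 libraries, and the 96 lists held 2848626 peaks. The median list held 46379 peaks in undifferentiated cells (n = 3), 26667 in macrophages (n = 21), 18873 in neutrophils (n = 21), 25666 in monocytes (n = 21) and 28225 in monocyte-derived macrophages (n = 15). Replicates of a group often differed many-fold, as in macrophages at 120 h (58236.7 ± 53903.3 peaks, SD, n = 3). The 4 lists under 3000 peaks were macrophage LPS 48 h replicate 1 (2817), neutrophil 120 h replicate 1 (2610), monocyte 24 h replicate 1 (615) and monocyte 48 h replicate 1 (2858).

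**Figure D1:**
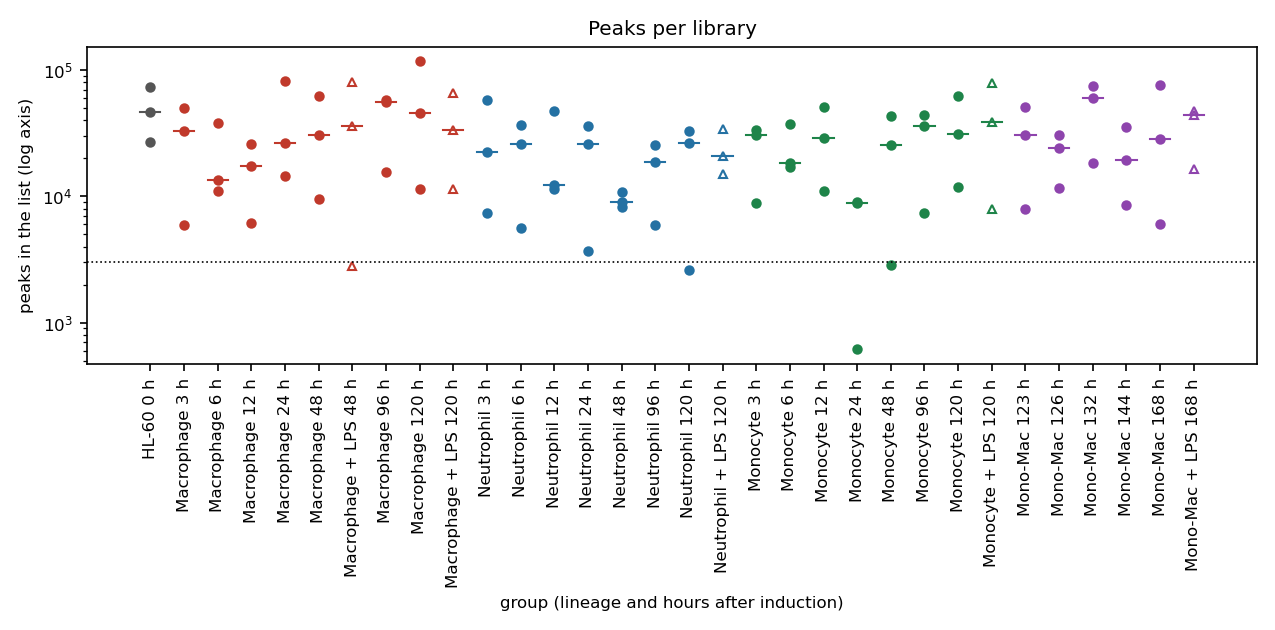
Number of peaks in each of the 96 libraries on a log axis, by group in order of lineage and time; each point is a library. Lists run from 615 to 117188 peaks, and replicates of a group often lie far apart.

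Neutrophil lists held 0.335 times as many peaks as undifferentiated lists, and late macrophage lists 1.92 times as many as early ones, both as ratios of geometric means. Neither of these nor any of the other 10 comparisons of list length passed the adjusted permutation test; the lowest adjusted p was 0.382. The percentage of peaks shorter than 500 bp was lower in macrophages than in neutrophils (21.9 ± 9.62% against 33.6 ± 12.1%, SD, n = 21 and 20, permutation test, adjusted p = 0.0145). It averaged 37.9 ± 20.5% in monocyte-derived macrophages and 21.3 ± 9.48% in macrophages of matched times (n = 15 each, adjusted p = 0.0775, not passed).

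Libraries of the same lineage and time resembled each other more than libraries of the same lineage at other times. The mean correlation of depth-adjusted detection was 0.128 over 72 pairs of the same time and 0.0595 over 604 pairs of other times (one-sided permutation test, p = 1e-05, the smallest possible). Within a time point, macrophages, neutrophils and monocytes were also closer to their own lineage (0.114 over 57 pairs) than to the others (0.00132 over 171 pairs, one-sided permutation test, p = 1e-05, the smallest possible). Monocyte-derived macrophages had the highest mean correlation within a time, 0.182, and neutrophils the lowest, 0.0800. These correlations were low, so single libraries of a group shared only a small part of their deviations.

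Monocyte-derived macrophages had a larger share of peaks near gene ends than late monocytes or direct macrophages. After adjustment for list length, 44.0 ± 3.30% of their peaks lay within 1 kb of a gene end, against 36.2 ± 2.55% in late monocytes (SD, n = 15 and 9, difference 7.80 points) and 35.6 ± 2.91% in macrophages of matched times (n = 15, difference 8.35 points). Both differences passed the permutation test (adjusted p = 0.00012 each), but neither did without adjustment for list length (6.103 and 6.145 points, adjusted p = 0.472 and 0.465). The share was also higher in macrophages than in monocytes (36.2 ± 3.11% against 33.7 ± 3.85%, n = 21 and 20, permutation test, adjusted p = 0.00788). That call was lost without replicate 1 (adjusted p = 0.0909) and without replicate 2 (0.222), and without adjustment for list length the difference turned (-1.15 points, 0.796). Late monocytes exceeded early ones by 3.70 points (36.2 ± 2.55% against 32.5 ± 3.26%, n = 9 each, exact permutation test, adjusted p = 0.0306). This call was lost without replicate 1, 2 or 3 (adjusted p = 0.307, 0.173 and 0.0831) and without adjustment for list length (0.581). The remaining 8 comparisons did not pass, late against early macrophages by a small margin (3.20 points, n = 9 each, exact permutation test, adjusted p = 0.0589).

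Macrophages and neutrophils, the end points of PMA and of retinoic acid with DMSO, were compared at matched times. Regions at several genes were open in nearly every macrophage library and in no neutrophil library. A region inside ANXA5, which encodes the phospholipid-binding protein annexin A5 (chromosome 4, 121690535 to 121691226), was detected in 20 of 21 macrophage and 0 of 20 neutrophil libraries (difference 0.92 ± 0.081, SE, adjusted p = 3.03e-13). The pattern was the same at LRRC4C (inside the gene, chromosome 11, 41306271 to 41306971, 21 of 21 against 0 of 20) and at SMIM21 (within 1 kb of a gene end, chromosome 18, 75408521 to 75409394, 21 of 21 against 0 of 20). A region 16640 bp from PIK3C3, which encodes an autophagy kinase (chromosome 18, 41938271 to 41938916), was detected in 20 of 21 against 0 of 20. The same counts held at RAB27B, a gene of vesicle secretion, and GSDMC, of the pore-forming gasdermin family. Peaks away from gene ends were denser on chromosome 18 than on the median chromosome in 92 of 92 libraries, and peaks were also dense in the part of chromosome 8 that holds GSDMC.

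Of 104 regions at retinoic acid targets, 21 were higher and 2 lower in macrophages (adjusted over the list alone, 21 and 2), 20.19% and 1.923% against 17.86% and 2.23% of all tested regions. A region inside RARG, the retinoic acid receptor gamma gene (chromosome 12, 53219138 to 53220150), was detected in 15 of 21 macrophage and 0 of 20 neutrophil libraries (difference 0.69 ± 0.0795, adjusted p = 1.09e-09). RARRES1 (12 of 21) and CRABP2, a cellular retinoic acid-binding protein gene (10 of 21), were also undetected in neutrophils. Macrophage markers had 31 regions higher and 2 lower of 119 (adjusted over the list alone, 31 and 3). Adhesion and cytoskeleton genes had 39 and 2 of 144 (over the list alone, 42 and 2), with CD9, a tetraspanin gene, in 11 of 21 against 0 of 20. Neutrophil granule genes had 9 higher and 4 lower of 54 (10 and 5), 16.67% and 7.407% of their regions. Among the higher ones was a region inside MPO, which encodes the granule enzyme myeloperoxidase (chromosome 17, 58272761 to 58274082, 13 of 21 against 0 of 20, adjusted p = 4.12e-08). As shares of all peaks, macrophage markers took 0.148 ± 0.0290% in macrophages and 0.102 ± 0.0268% in neutrophils (SD, n = 21 each, permutation test, adjusted p = 0.00144). Shares were also higher for AP-1 and immediate-early genes (0.298% against 0.244%, permutation test, adjusted p = 0.00144; 0.09713 without replicate 1, with a difference of 0.02501 points) and LPS and NF-kB response genes (0.240% against 0.181%, adjusted p = 0.00396). Those of adhesion and cytoskeleton genes (0.214% against 0.169%, 0.00589), monocyte markers (0.102% against 0.0726%, 0.00876) and retinoic acid targets (0.149% against 0.122%, 0.0139) were higher by the same test. B cell markers took a smaller share in macrophages (0.0257% against 0.0399%, permutation test, adjusted p = 0.0139). Of these 7 calls, that of macrophage markers held in 3 of 3 fits that left out a replicate number and that of AP-1 and immediate-early genes in 2. The calls of LPS, adhesion, retinoic acid and B cell lists held in 1 each and that of monocyte markers in 0. Neutrophil 3 h replicate 1 stood apart, with 5.8291% of its peaks near gene ends and 0.068578% at AP-1 and immediate-early genes, both before adjustment. Over all comparisons 40 of 216 list shares passed, of which 16, 13 and 3 also passed without replicate 1, 2 and 3.

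Fewer regions went the other way. PLXNA1, a semaphorin receptor gene (37644 bp outside, 4 of 21 against 15 of 20, adjusted p = 1.87e-05), MACC1 (3 of 21 against 14 of 20), ANKEF1 (1 of 21 against 10 of 20) and NFATC1, a transcription factor gene (4 of 21 against 13 of 20), were detected more often in neutrophils. In all, limma called 10387 regions higher and 1297 lower in macrophages, of 58154 tested. The method leaned towards higher calls, since 64.5% of the regions recovered in the simulation were higher. With the logistic expectation in place of the spline the split was 5538 and 3333, and leaving out a replicate number reduced the calls to between 3280 and 7372.

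**Figure D2:**
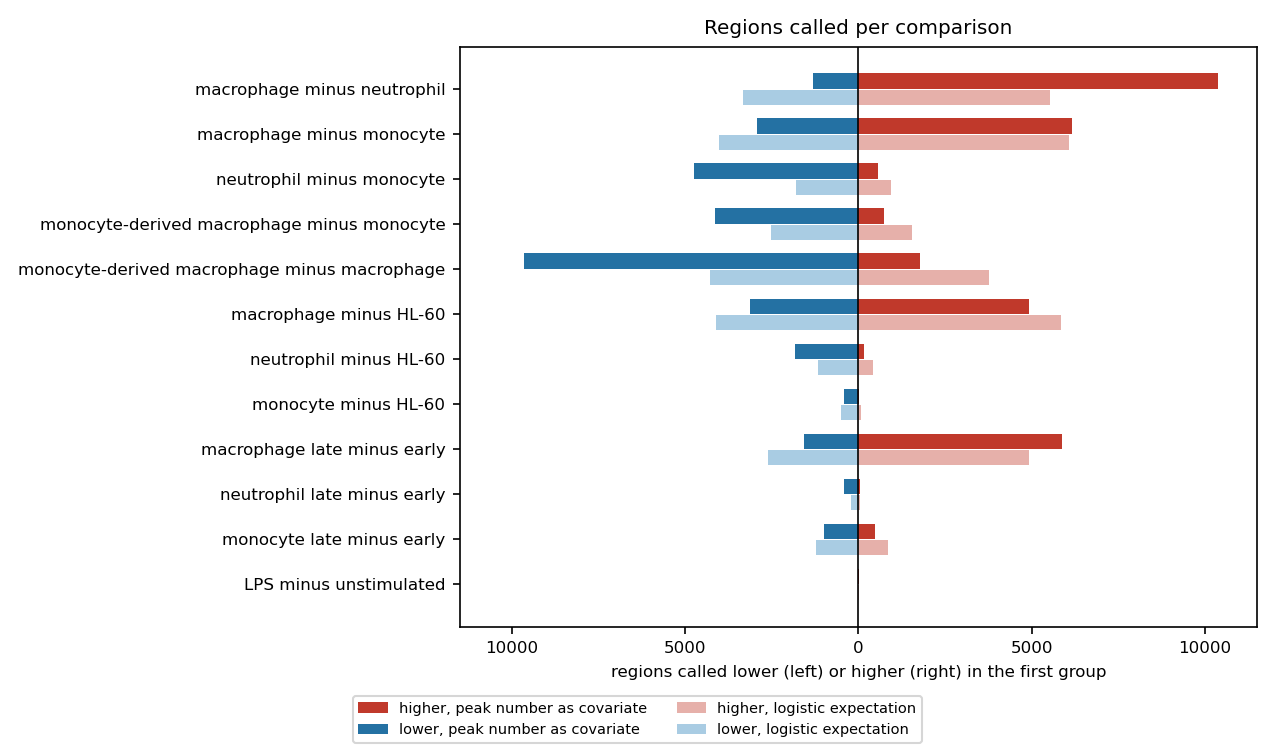
Number of regions called higher (to the right) and lower (to the left) in each of the 12 comparisons, with the spline of list length (dark bars) and with the logistic expectation (pale bars). Macrophages had 10387 regions higher than neutrophils with the spline and 5538 with the logistic expectation.

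Macrophages and monocytes, compared at matched times, differed at PIK3C3 (20 of 21 macrophage and 0 of 19 monocyte libraries, difference 0.96 ± 0.0548, adjusted p = 1.71e-21). LRRC4C (21 of 21 against 0 of 19), MRPL39, a mitochondrial ribosomal protein gene (19 of 21 against 0 of 19), and CDK5RAP2, a centrosome gene (18 of 21 against 1 of 19), differed likewise. BIRC3, an inhibitor of apoptosis gene (12 of 21 against 0 of 19), and a region inside CDK6, a cell cycle kinase gene (16 of 21 against 0 of 19), were also higher in macrophages. Monocytes had regions that macrophages lacked. A region inside ALOX5AP, a gene of leukotriene synthesis (chromosome 13, 30737389 to 30738413), was detected in 0 of 21 macrophage and 13 of 19 monocyte libraries (difference -0.71 ± 0.105, adjusted p = 7.93e-07). BST1 (2 of 21 against 14 of 19), FN1, the fibronectin gene (4 of 21 against 15 of 19), and MARCO, a scavenger receptor gene (3 of 21 against 13 of 19), were lower in macrophages. So were the transcription factor genes IRF5 (6 of 21 against 16 of 19) and RUNX1 (6 of 21 against 15 of 19). Lower regions at vitamin D targets included TREM1 (7 of 21 against 17 of 19) and CYP24A1, which encodes the enzyme that inactivates vitamin D (within 1 kb of a gene end, chromosome 20, 54173592 to 54175031, 1 of 21 against 11 of 19, adjusted p = 8.86e-05).

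Adhesion and cytoskeleton genes had 30 regions higher and 5 lower in macrophages (over the list alone, 34 and 8), 20.83% and 3.472% of their regions. They took a larger share of peaks (0.214 ± 0.0422% against 0.173 ± 0.0366%, SD, n = 21 and 20, permutation test, adjusted p = 0.00617). That call held in 1 of 3 fits that left out a replicate number. Housekeeping genes also took a larger share (0.109% against 0.0906%, adjusted p = 0.0377, permutation test). Vitamin D targets (0.0998% against 0.120%, adjusted p = 0.043) and neutrophil granule genes (0.0626% against 0.0727%, adjusted p = 0.0419) took smaller shares, and these permutation calls and that of housekeeping genes were lost in 7 or 8 of 10 other settings. Macrophage markers split into 14 higher and 8 lower (15 and 9), and vitamin D targets into 10 and 8 (12 and 9). The higher ones were 11.76% and 12.05% of the regions of these lists and the lower ones 6.723% and 9.639%. Of all tested regions, 10.58% were higher and 5.023% lower. The test called 6155 regions higher and 2921 lower. With the percentage of short peaks as a second covariate the split was 4975 and 5038, without adjustment for list length 5838 and 866, and leaving out a replicate number left 2446 to 3204 calls.

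More regions were called lower than higher in neutrophils against monocytes. The method itself leaned this way, since in the simulation, with as many raised as lowered regions, 38.0% of the recovered ones were higher. KCTD1 (inside the gene, chromosome 18, 26458362 to 26459049) was detected in 1 of 20 neutrophil and 17 of 19 monocyte libraries (difference -0.80 ± 0.0892, adjusted p = 1.13e-08). GRK5, a receptor kinase gene, was detected in 3 of 20 against 18 of 19, and a region 33425 bp from KIAA0408 in 0 of 20 against 15 of 19. A region inside MARCO (chromosome 2, 118945631 to 118946461) was detected in 0 of 20 against 10 of 19 (adjusted p = 1.77e-05) and one inside SERPINB2, a protease inhibitor gene, in 0 of 20 against 11 of 19. TFEC, a transcription factor gene, was detected in 2 of 20 against 16 of 19, and the apoptosis regulator BCL2 in 4 of 20 against 17 of 19. Macrophage markers had 0 regions higher and 14 lower (over the list alone, 0 and 15), myeloid transcription factors 0 and 20 (0 and 20), and progenitor and leukaemia genes 1 and 18 (1 and 19). The lower ones were 11.76%, 9.174% and 12.77% of the regions of these lists, against 8.177% of all tested. As shares of peaks, progenitor and leukaemia genes were lower in neutrophils (0.221 ± 0.0563% against 0.274 ± 0.0501%, SD, n = 21 and 20, permutation test, adjusted p = 0.00617). Macrophage markers (0.102% against 0.134%, 0.00617), LPS and NF-kB response genes (0.181% against 0.232%, 0.0125) and vitamin D targets (0.0945% against 0.120%, 0.0419) were lower too, and B cell markers were higher (0.0399% against 0.0256%, 0.00966), by permutation tests. In the 3 fits that left out a replicate number, the call of macrophage markers held in 2, those of progenitor, LPS and B cell lists in 1 each and that of vitamin D targets in 0 (and in 4 of 10 other settings). None of these lists was called without replicate 3.

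Neutrophil granule genes gave 3 regions higher and 6 lower in neutrophils (4 and 8), 5.556% and 11.11% against 0.9509% and 8.177% of all tested regions. The higher ones included regions near CEACAM8 (5 of 20 against 0 of 19, adjusted p = 0.0264) and inside LTF, the lactoferrin gene (6 of 20 against 0 of 19, adjusted p = 0.0293). Both calls ended with the percentage of short peaks as a second covariate. Within 1 kb of a gene end lay 28.6% of the 553 higher regions, 2.67% of the 4755 lower ones and 18.7% of all tested. The logistic expectation gave 927 higher and 1796 lower, and leaving out a replicate number left 1365 to 2839 calls.

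Late monocytes and the macrophages derived from them were compared in cells already treated with vitamin D3. Their times in culture do not overlap (123 to 168 h against 48 to 120 h), so time changed along with PMA. A region 1701 bp from DPP4, the dipeptidyl peptidase gene (chromosome 2, 162075500 to 162076332), was detected in 7 of 8 late monocyte libraries and 0 of 15 libraries of monocyte-derived macrophages (difference -0.89 ± 0.107, adjusted p = 4.69e-07). RARB, a retinoic acid receptor gene, lost a region inside the gene (chromosome 3, 25294213 to 25295092, 8 of 8 to 2 of 15, adjusted p = 6.49e-05). A region 17670 bp from ADGRE5, which encodes the adhesion receptor CD97, went the other way (chromosome 19, 14363425 to 14364122, 0 of 8 to 10 of 15, adjusted p = 0.000139), as did one at the end of SEMA6B, a semaphorin gene (0 of 8 to 7 of 15, adjusted p = 0.00546). Both are on the list of vitamin D targets, which had 3 regions higher and 9 lower of 83 (over the list alone, 4 and 11), 3.614% and 10.84% against 1.271% and 7.11% of all tested regions. Progenitor and leukaemia genes had 1 region higher and 14 lower (over the list alone, 3 and 17), 0.7092% and 9.929% of their regions. KIT, the stem cell factor receptor gene (7 of 8 to 1 of 15), and CDK6 (6 of 8 to 0 of 15) were among them, with calls lost without replicate 3. In the LPS-treated monocyte-derived macrophages, which this comparison leaves out, RARB and CDK6 were detected in 3 of 3 libraries and KIT and FN1 in 2 of 3. Macrophage markers had 2 higher and 12 lower (2 and 14), 1.681% and 10.08% of their regions. Among them was FN1, in 6 of 8 against 1 of 15, a call lost without replicate 2. Adhesion and cytoskeleton genes took a larger share of peaks in monocyte-derived macrophages (0.246 ± 0.0356% against 0.194 ± 0.0416%, SD, n = 15 and 9, permutation test, adjusted p = 0.0273), as did housekeeping genes (0.131% against 0.0970%, permutation test, adjusted p = 0.0225). These calls held in 0 and 1 of 3 fits that left out a replicate number, and in 4 and 5 of 10 other settings. Limma called 739 regions higher and 4135 lower, of which 30.6% and 2.32% lay near a gene end. The method leaned this way, since 33.9% of the regions recovered in the simulation were higher. The logistic expectation gave 1557 and 2537, and only 79 regions were called without replicate 2 and 224 without replicate 3.

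Monocyte-derived macrophages and macrophages made directly from HL-60 cells were matched by time after PMA, 3 to 48 h. Regions inside EXT1, a heparan sulphate synthesis gene (chromosome 8, 117881273 to 117882101, 1 of 15 against 14 of 15, difference -0.90 ± 0.103, adjusted p = 9.15e-09), CRIM1 (1 of 15 against 13 of 15) and KDM4C, a histone demethylase gene (2 of 15 against 14 of 15), were detected mostly in the direct macrophages. LPS-treated monocyte-derived macrophages, not part of this comparison, had EXT1 and CRIM1 in 3 of 3 libraries and KDM4C in 2 of 3. Of the retinoic acid targets, RARRES1 was detected in 0 of 15 against 7 of 15 (adjusted p = 1.43e-05) and RARB, a retinoic acid receptor gene, in 2 of 15 against 11 of 15 (adjusted p = 3.7e-05). This list had 2 regions higher and 17 lower (over the list alone, 3 and 20), and the 16.35% lower were close to the 16.6% of all tested regions. The figures were 4 and 22 (4 and 22) for progenitor and leukaemia genes. Macrophage markers had 5 and 18 (7 and 20), with PLIN2, a lipid droplet gene, in 5 of 15 against 13 of 15. The lower ones were 15.6% and 15.13% of the regions of these lists, also near the 16.6% of all tested. The higher ones were 2.837% and 4.202%, against 3.075%. Vitamin D targets went the other way, 14 higher and 6 lower (14 and 7), 16.87% and 7.229% of their regions. ADGRE5 was detected in 10 of 15 against 2 of 15 (adjusted p = 8.84e-05). NAPSA, an aspartic protease gene (within 1 kb of a gene end, chromosome 19, 50368459 to 50369607), was detected in 11 of 15 against 0 of 15 (adjusted p = 5.28e-06). CAMP, the cathelicidin gene and a vitamin D target (14 of 15 against 6 of 15), ICAM1 (15 of 15 against 6 of 15), and JUND, an AP-1 subunit gene (12 of 15 against 2 of 15), were also higher. The calls were lost without replicate 1 for CAMP and ICAM1 and without replicate 2 for JUND.

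The share of peaks at vitamin D targets was 0.158 ± 0.0189% in monocyte-derived macrophages and 0.0923 ± 0.0318% in direct ones (SD, n = 15 each, permutation test, adjusted p = 0.00144), and this call held in 10 of 10 other settings. Against late monocytes, which had also received vitamin D3, the share of this list in monocyte-derived macrophages was not called. AP-1 and immediate-early genes (0.358% against 0.291%, adjusted p = 0.00589), erythroid and megakaryocyte markers (0.0232% against 0.0149%, 0.00876), housekeeping genes (0.131% against 0.107%, 0.0225), B cell markers (0.0374% against 0.0246%, 0.0345) and adhesion and cytoskeleton genes (0.246% against 0.206%, 0.0412) took larger shares by permutation tests. Of these 5 calls, that of housekeeping genes held in 1 of 3 fits that left out a replicate number, and the other 4 in 0 of 3. With peaks of at least 500 bp the AP-1 difference turned (-0.02359 points). Lists as unlike as housekeeping, B cell and AP-1 genes moved the same way, in libraries that also had more of their peaks near gene ends. Whether these rises are specific to the lists was not tested. Progenitor and leukaemia genes took a smaller share (0.215% against 0.266%, permutation test, adjusted p = 0.00589), a call that held in 2 of 3 fits that left out a replicate number. Limma called 1788 regions higher and 9652 lower, and 38.2% of the higher and 3.24% of the lower ones lay near a gene end. Here too the method leaned towards lower calls, with 33.6% of the regions recovered in the simulation higher. The logistic expectation gave 3763 and 4295, and the percentage of short peaks as a second covariate 559 and 1421. Leaving out a replicate number left 1946 to 7183 calls.

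**Figure D3:**
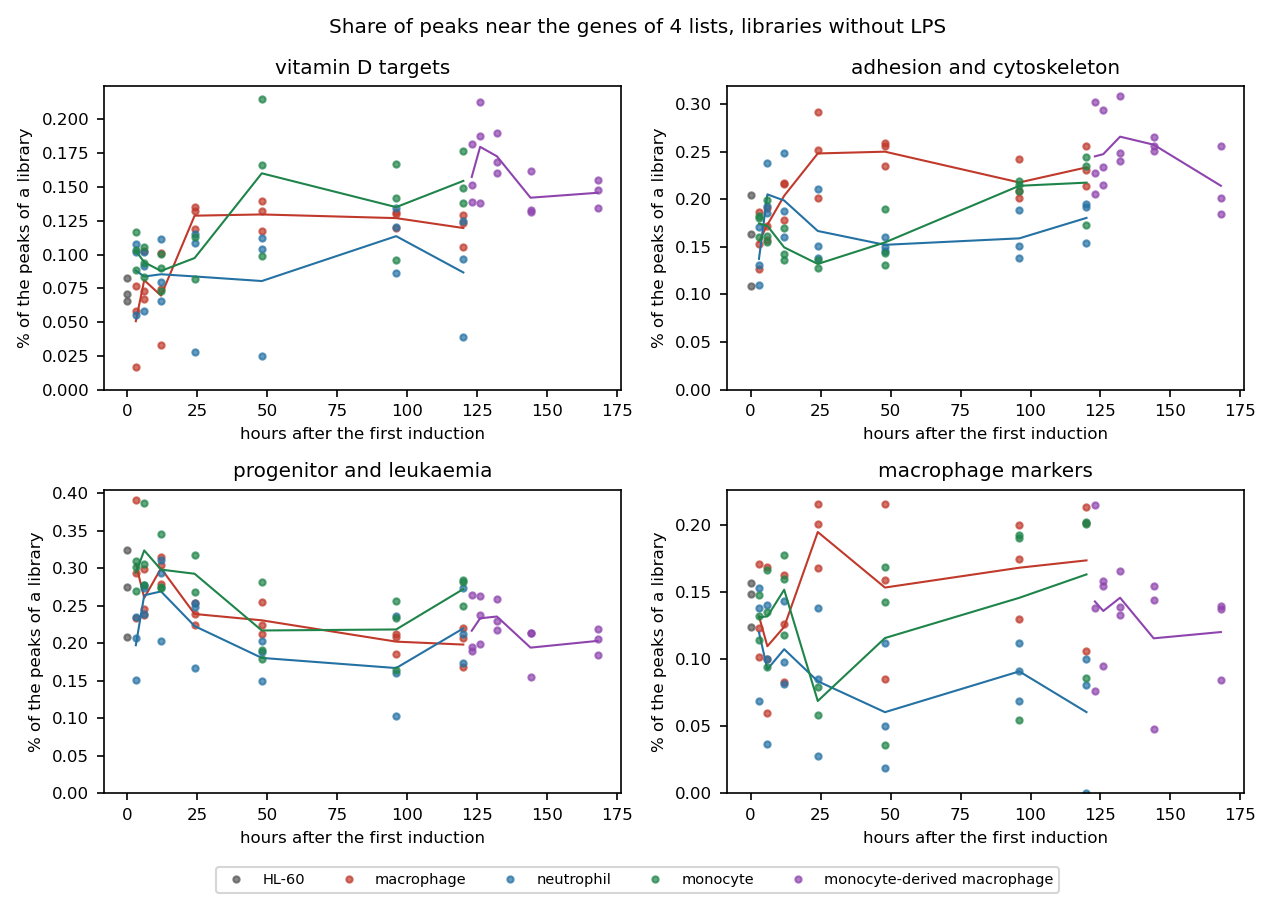
Share of each library's peaks assigned to 4 gene lists, in percent, against time in hours; points are libraries with at least 1000 peaks and without LPS, lines join group means. Vitamin D targets average 0.158% in monocyte-derived macrophages and 0.0923% in direct macrophages of matched times.

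Against undifferentiated HL-60 cells, each lineage lost regions that all 3 undifferentiated libraries held. A region inside GRAMD1B (chromosome 11, 123480210 to 123481015) was detected in 3 of 3 undifferentiated, 0 of 21 macrophage (difference -0.97 ± 0.137, adjusted p = 1.02e-05) and 0 of 20 neutrophil libraries (-0.94 ± 0.14, adjusted p = 7.73e-05). MECOM, a haematopoietic stem cell transcription factor gene, also went from 3 of 3 to 0 of 21 and 0 of 20. Macrophages lost a region inside ERG, an ETS factor gene (chromosome 21, 38386829 to 38387463, 3 of 3 to 0 of 21, adjusted p = 0.000416). A region 23976 bp from RUNX2 was detected in 0 of 21 macrophage, 1 of 20 neutrophil (adjusted p = 0.000845) and 4 of 19 monocyte libraries (adjusted p = 0.0111). One at IFIT1, an interferon-induced gene, was detected in 1 of 21, 0 of 20 and 5 of 19. The monocyte calls of both were lost with libraries of at least 10000 peaks. Monocytes lost regions near HTN3 (0 of 19, adjusted p = 0.0017) and inside SOX6 (1 of 19) and KHDRBS2 (1 of 19).

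Macrophages also gained regions over undifferentiated cells. RUBCNL, an autophagy gene (20 of 21 against 0 of 3, difference 1.17 ± 0.195, adjusted p = 0.000105), COL8A1, a collagen gene (20 of 21), EMP1, a membrane protein gene (18 of 21), and TNIP2, a gene of NF-kB signalling (18 of 21), were undetected in the undifferentiated libraries. Adhesion and cytoskeleton genes had 23 regions higher and 5 lower (over the list alone, 34 and 7), macrophage markers 16 and 5 (23 and 8), and vitamin D targets 11 and 1 (12 and 1). The higher ones were 15.97%, 13.45% and 13.25% of the regions of these lists, against 8.469% of all tested. The lower ones were 3.472%, 4.202% and 1.205%, against 5.369%. In neutrophils progenitor and leukaemia genes had 0 higher and 8 lower (1 and 14), with 5.674% lower against 3.14% of all tested. In monocytes, myeloid transcription factors had 0 higher and 2 lower (0 and 2), with 0.9174% lower against 0.7377%. No list share passed against undifferentiated cells; the smallest adjusted p for interferon response genes in any of the 12 comparisons, 0.327, was among these. In all, 4925 regions were higher and 3122 lower in macrophages, 168 and 1826 in neutrophils, and 25 and 429 in monocytes. Of the regions recovered in the simulation, 48.1%, 28.6% and 47.9% were higher, so the method leaned towards lower calls in neutrophils. In macrophages the split was 554 and 2461 without adjustment for list length and 6411 and 2525 with the percentage of short peaks. It was 407 and 1157 in neutrophils with the logistic expectation and 54 and 168 in monocytes with the percentage of short peaks. The same 3 undifferentiated libraries entered these comparisons, so the calls are not independent. The macrophage split was 123 and 167 without replicate 1, 401 and 255 without replicate 2, and 1674 and 227 without replicate 3. Leaving out a replicate number left 290 to 1901 calls for macrophages, 0 to 313 for neutrophils and 0 to 8 for monocytes.

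Late macrophages gained regions that no early macrophage library had. A region inside LCP2, a signalling adaptor gene (chromosome 5, 170289640 to 170290301), was detected in 9 of 9 late and 0 of 9 early libraries (difference 0.99 ± 0.0692, adjusted p = 1.45e-17). The same counts held at SAMD13, RNGTT and POC1B-DUSP6 and for a region near CD9 (chromosome 12, 6182046 to 6183600, adjusted p = 1.17e-13). The vitamin D receptor gene VDR (inside the gene, chromosome 12, 47882651 to 47883274), the lipid-sensing receptor gene PPARG (inside the gene, chromosome 3, 12405563 to 12406191) and CRABP2 were each detected in 8 of 9 against 0 of 9, with adjusted p = 6.95e-09, 2.67e-07 and 5.96e-10. MPO was detected in 9 of 9 against 1 of 9, and GZMB, the granzyme B gene, in 7 of 9 against 0 of 9. CCDC178 (0 of 9 against 8 of 9) and IPMK, an inositol kinase gene (1 of 9 against 8 of 9), were lower late.

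By list, late macrophages had 26 regions higher and 1 lower at adhesion and cytoskeleton genes (over the list alone, 30 and 2) and 18 and 2 at retinoic acid targets (21 and 2). They had 13 and 1 at vitamin D targets (17 and 1) and 25 and 5 at myeloid transcription factors (25 and 5). In the same order, the higher ones were 18.06%, 17.31%, 15.66% and 11.47% of the regions of these lists, against 10.12% of all tested. The lower ones were 0.6944%, 1.923%, 1.205% and 2.294%, against 2.7%. Shares rose for vitamin D targets (0.0698 ± 0.0184% to 0.121 ± 0.00935%, SD, n = 9 each, exact permutation test, adjusted p = 0.00178), retinoic acid targets (0.118% to 0.178%, 0.00178) and adhesion and cytoskeleton genes (0.175% to 0.240%, 0.00589). By the same exact permutation test they rose for AP-1 and immediate-early genes (0.271% to 0.318%, 0.00833), T and NK cell markers (0.0257% to 0.0457%, 0.0335), mature neutrophil genes (0.0588% to 0.0781%, 0.0419) and myeloid transcription factors (0.275% to 0.341%, 0.0476). Progenitor and leukaemia genes fell from 0.290 ± 0.0534% to 0.206 ± 0.0235% (n = 9 each, exact permutation test, adjusted p = 0.00589). In the 3 fits that left out a replicate number, the calls of vitamin D and retinoic acid targets held in 2. Those of adhesion, AP-1 and mature neutrophil genes (lowest difference 0.007605 points) held in 1, and those of T and NK cell markers, myeloid transcription factors and progenitor genes in 0. No late macrophage list was called without replicate 3. Limma called 5885 regions higher and 1570 lower. The split was 4927 and 2622 with the logistic expectation, 5075 and 2641 with the percentage of short peaks and 9729 and 117 without adjustment for list length. Between 967 and 3336 regions were called when a replicate number was left out.

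Late neutrophils mainly lost regions. A region inside IL1RAP, an interleukin 1 receptor subunit gene (chromosome 3, 190566246 to 190567012), went from 8 of 9 early to 0 of 8 late libraries (difference -0.87 ± 0.104, adjusted p = 2.15e-07). One at the end of CTSG, which encodes the granule protease cathepsin G (chromosome 14, 24576000 to 24577274), went from 7 of 9 to 0 of 8 (adjusted p = 0.00422). IKZF1, the Ikaros gene (7 of 9 to 1 of 8), ID1 (7 of 9 to 0 of 8) and BCL2 (8 of 9 to 0 of 8) were lower, and OAS3, an interferon-induced gene, was higher (0 of 9 to 5 of 8, adjusted p = 0.0189). Progenitor and leukaemia genes had 0 regions higher and 4 lower (over the list alone, 0 and 4), and neutrophil granule genes 0 and 1 (0 and 4). All of these region calls, 35 higher and 422 lower, were fragile; without replicate 3 none of the genes named here was called, and the total was 2 to 95 when a replicate number was left out.

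Late monocytes gained the region near DPP4 (0 of 9 to 7 of 8, difference 0.84 ± 0.118, adjusted p = 2.17e-05). IL4R, the interleukin 4 receptor gene (0 of 9 to 7 of 8), THEMIS2 (1 of 9 to 8 of 8) and the immediate-early gene NR4A1 (0 of 9 to 5 of 8) gained regions, and LDB1 lost one (9 of 9 to 1 of 8). These calls were lost without replicate 3. Vitamin D targets had 7 regions higher and 0 lower (over the list alone, 10 and 0), and their share rose from 0.0916 ± 0.0154% to 0.150 ± 0.0455% (SD, n = 9 each, exact permutation test, adjusted p = 0.00652). Shares also rose for AP-1 and immediate-early genes (0.245% to 0.319%, 0.0181), B cell markers (0.0193% to 0.0327%, 0.0139) and mature neutrophil genes (0.0643% to 0.0996%, 0.0419) by exact permutation tests. Progenitor and leukaemia genes fell (0.304% to 0.238%, exact permutation test, adjusted p = 0.0156). Leaving out a replicate number kept the calls of AP-1 genes and B cell markers in 1 of 3 fits and those of vitamin D targets, mature neutrophil genes and progenitor genes in 0 of 3. None was kept without replicate 3. Limma called 470 regions higher and 1004 lower, against 485 and 536 with the percentage of short peaks as a second covariate. Without replicate 2 the total was 10 and without replicate 3 it was 2. The share of peaks at cell cycle genes passed in none of the 12 comparisons, with a smallest adjusted p of 0.231 by permutation test, although single regions of this list were called.

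**Figure D4:**
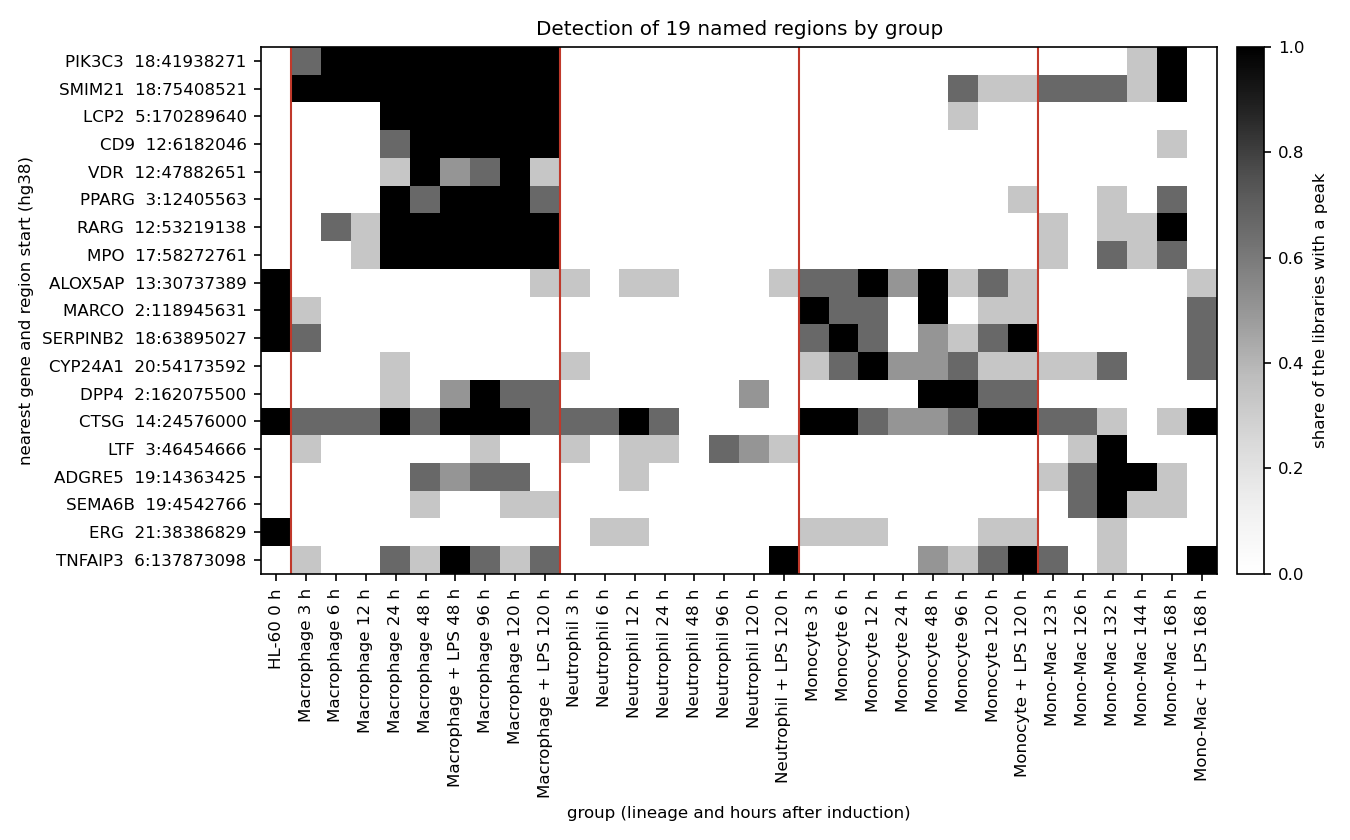
Fraction of retained libraries with a peak (grey scale, 0 to 1) for 19 named regions across the 32 groups, ordered by lineage and time. The regions at LCP2, CD9 and VDR are empty in macrophages at 3, 6 and 12 h.

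LPS was compared with no LPS within 5 conditions. The clearest change was a region inside TNFAIP3, which encodes the NF-kB inhibitor A20 (chromosome 6, 137873098 to 137873839), detected in 13 of 14 LPS and 4 of 14 unstimulated libraries (difference 0.66 ± 0.114, adjusted p = 0.00612). It was seen in 3 of 3 LPS-treated libraries of neutrophils, monocytes and monocyte-derived macrophages each. Regions inside LYN, a SRC family kinase gene (14 of 14 against 6 of 14, adjusted p = 0.0286), and near LYZ, the lysozyme gene (9 of 14 against 2 of 14, adjusted p = 0.0447), also passed. LPS and NF-kB response genes had 1 region higher and 0 lower (over the list alone, 7 and 0), and their share of peaks rose from 0.227 ± 0.0552% to 0.271 ± 0.0368% (SD, n = 15 each, permutation test, adjusted p = 0.0478). In all, limma called 27 regions higher and 1 lower, with 4644 at an unadjusted p under 0.05. None of the named calls held without each replicate number in turn, which left 0 or 1 region, and the share was called in 5 of 10 other settings. Without the condition of monocyte-derived macrophages, 5 regions were higher and 0 lower, and the calls at TNFAIP3 (10 of 11 against 4 of 11, adjusted p = 0.157), LYN (0.305) and LYZ (0.578) were lost. The share of LPS and NF-kB response genes was not retested without that condition. Within single conditions, 270 regions were higher and 99 lower in monocyte-derived macrophages, whose LPS-treated libraries did not resemble the untreated ones, as given below. The counts were 135 and 60 in neutrophils (3 LPS-treated and 2 untreated libraries) and 4 and 0 in macrophages at 48 h (2 and 3 libraries). They were 0 in macrophages at 120 h and in monocytes (3343 and 1979 at an unadjusted p under 0.05 by limma). Other splits were not counted for single conditions.

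CDKN2A had been set as a check of the line because its locus was listed in advance as deleted, so that no peaks were expected. Within 1 kb of it (chromosome 9, 21967752 to 21995324), 198 peaks lay in 78 of 96 libraries, including 3 of 3 undifferentiated ones, and their density was 669.6 per 100 kb against 83.37 in the neighbourhood. The expectation was not met, and copy number was not measured.

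**Figure D5:**
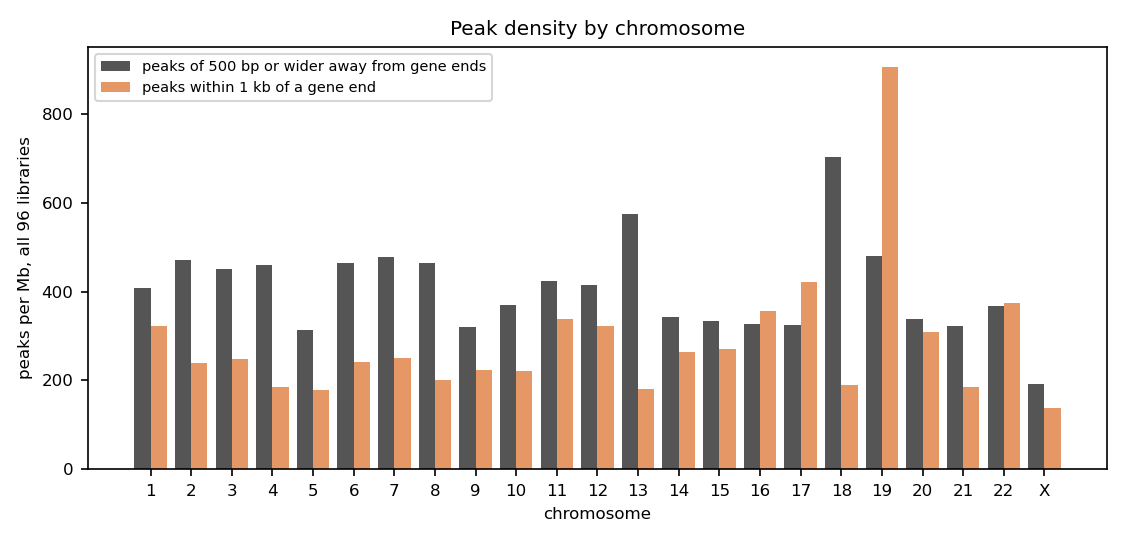
Peaks of at least 500 bp away from gene ends and peaks within 1 kb of a gene end, per megabase of each chromosome, as bars from 0 summed over all libraries. Chromosome 18 has 1.81 times the density of the median of the other chromosomes in the former and 0.758 times in the latter.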

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

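The tests of other splits of the libraries, for the differences between lineages and between LPS conditions, were chosen after the results were seen, as were the alternative settings of the lineage differences and the count of gains and losses among them.

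The change from early to late times differed between lineages, as measured by tests of the difference itself. The late minus early difference was higher in macrophages than in monocytes at 2856 regions and lower at 247, 3103 in all. Of the 2856, 2556 were also called as gained late in macrophages, 156 as lost late in monocytes, 9 of them as both, and 153 as neither. As examples, a region inside LCP2 was detected in 9 of 9 late macrophage and 1 of 8 late monocyte libraries, and one near CD9 in 9 of 9 and 0 of 8, while early libraries of both lineages had neither (adjusted p of the difference = 3.45e-09 and 6.05e-08). Against neutrophils the figures were 1635 and 65, 1700 in all. Neutrophils and monocytes differed at 9 regions, 2 higher and 7 lower, with 3752 at an unadjusted p under 0.05 by limma. No other split reached the real count for macrophages against neutrophils (real value 1700, highest of the other splits 1366, 1 of 100 splits as large) and against monocytes (3103, highest other 1887, 1 of 100). Chance is thus excluded only at the level of 1 in 100 that these splits allow. For neutrophils against monocytes 3 of 100 splits were as large, the real one included (9, highest other 14). Other splits thus reached the real count, so chance is not excluded there. The count was 24 without replicate 1 and 0 without replicate 2 or 3 (2688 and 2139 at an unadjusted p under 0.05 by limma). With libraries of at least 10000 peaks the count was 150 (7 higher, 143 lower). For macrophages against neutrophils the count was 176, 428 and 101 without replicates 1, 2 and 3, and 232 with the logistic expectation. With the percentage of short peaks as a second covariate it was 1042 (926 higher, 116 lower).

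The higher late minus early difference of macrophages over monocytes was weighed against 3 technical explanations. If the linear treatment of list length were the cause, the logistic expectation should have removed the excess of positive differences, but 80.02% of its 1892 calls were positive, 1368 of them called as macrophage gains. With the percentage of short peaks as a second covariate 1648 regions were still higher, 1557 of them macrophage gains, which argues against short peaks as the whole cause. With libraries of at least 10000 peaks 2239 regions were higher, 2033 of them gains. That filter kept late macrophage lists of 11466 to 117188 peaks and early ones of 11124 to 50250. It did not make list lengths equal, so it cannot decide whether longer late lists were a cause. Leaving out replicates 1, 2 and 3 reduced the calls to 369, 655 and 105, so the size depends on the replicates included. Under these tests a stronger late opening in macrophages, the lineage named by the design, stays open as a hypothesis that may account for the pattern.

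The response to LPS differed from that of the other conditions at 23 regions in monocyte-derived macrophages at 168 h (8 higher, 15 lower), 5 in neutrophils at 120 h (3 and 2) and 2 in macrophages at 48 h (2 and 0). Chance cannot be excluded for any of them. The highest count among the other splits was 828 for monocyte-derived macrophages (10 of 100 splits as large), 181 for neutrophils (28 of 100) and 1305 for macrophages at 48 h (73 of 100). Splits with many times the real count point to a structure of the samples, which was not identified. The LPS-treated monocyte-derived macrophages did not resemble the untreated ones, as given below.

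Peaks on unplaced, random or alternate contigs entered no comparison. They numbered 32038, and their share of the list was above the highest undifferentiated library (0.986%) in 66 of 89 other libraries, with a median of 1.11% and a maximum of 3.01%.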

How the results depend on the processing

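Alternatives chosen after the data were seen were peaks of at least 500 bp only, the percentage of short peaks as a covariate, leaving out libraries with over 50% short peaks, the logistic expectation, leaving out monocyte-derived macrophages from the LPS comparison, and all settings of the differences between lineages. Of 291 named regions, 133 had a value in every setting, since settings with fewer libraries or peaks, or with 50% overlap, left the others untested in at least 1. Of these 133, 56 kept direction and call throughout and 83 in all settings but leaving out replicates, and of 241 with a value for each replicate number left out, 107 kept them. Read depth is unknown, so a region missing from a short list is not shown to be absent. Most counts of regions fell when a replicate number was left out. Unless the setting itself removes samples, peaks or regions, the cause of a change was not tested. Filters on peak scores, equal lists of best-scored peaks and motif shares were not run. Comparisons not named under a setting, here or in the sections above, stayed within 1.5 times the reported count, or kept direction and call.

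In no comparison did every pair of the same replicate number correlate over 0.1, so the numbers were not taken to pair the samples. The rule was hard to meet, since libraries of the same lineage and time averaged only 0.128. Failing it does not show that the numbers carry no structure. In monocyte-derived macrophages the percentage of short peaks was higher in replicate 3 than in replicate 1 at every time. It was 51.5% against 11.6% at 123 h and 73.5% against 13.1% at 168 h. Direct macrophages had the reverse order at 6, 12 and 24 h. For macrophage against neutrophil, libraries of the same number had a mean correlation of deviations of 0.0053, those of other numbers -0.00284, only 7 of 140 pairs exceeded 0.1, and 11 of 21 macrophage libraries were closer to their own number. Some comparisons leaned further that way: 11 of 15 monocyte-derived macrophage libraries against macrophages and 14 of 21 macrophage libraries against undifferentiated cells were closer to their own number, and 12% of pairs exceeded 0.1 in the former. In monocytes against undifferentiated cells it was 3 of 19. With the replicate block the counts of called regions were 11473, 9030, 5431, 5101, 11716, 8029, 1901, 432, 7432, 452, 1418 and 30 in the order of the report, all within 1.5 times the counts without it. It ended the calls of 3 named regions (RNASE2 in neutrophils against monocytes, ZEB2 in monocytes against undifferentiated cells, IKZF2 in late monocytes) and of 1 of 40 list shares (myeloid transcription factors in late macrophages, adjusted p = 0.05483). One share not called in the report passed with it (erythroid and megakaryocyte genes, neutrophil against monocyte, 0.0108 points).

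Region counts by setting were as follows. With no minimum list length, late neutrophils gave 175 calls and LPS 5. With libraries of at least 10000 peaks, neutrophils and monocytes against undifferentiated cells gave 1130 and 93, late neutrophils 686 and LPS 56. Without adjustment for list length, calls numbered 2777 for neutrophil against monocyte, 1252 and 2191 for monocyte-derived macrophages against monocytes and macrophages, 3015, 9461 and 957 for macrophages, neutrophils and monocytes against undifferentiated cells, 40 and 103 for late neutrophils and monocytes, and 0 for LPS (2282 at an unadjusted p under 0.05 by limma). With regions in at least 20 libraries they were 6579 and 3522 (1858 higher, 1664 lower) for macrophages against neutrophils and monocytes, 1984, 82 (18 and 64) and 0 (3128 unadjusted) for macrophages, neutrophils and monocytes against undifferentiated cells, 1981 (1221 and 760) and 958 for late macrophages and monocytes, and 9 for LPS, with fewer regions tested. With peaks of at least 500 bp they were 7658 and 3369 for macrophages and monocytes against neutrophils, 2919 (882 and 2037) and 6735 (2550 and 4185) for monocyte-derived macrophages against monocytes and macrophages, and 1138 (215 and 923) for neutrophils against undifferentiated cells. The split there also moved to 5174 and 3806 for macrophages against monocytes, 6313 and 2499 and 135 and 333 for macrophages and monocytes against undifferentiated cells, 4607 and 2401 for late macrophages and 85 and 358 for late neutrophils. With short peaks as a covariate they were 4067, 1768, 2086 and 1980 for macrophage against neutrophil, neutrophil against monocyte and monocyte-derived macrophage against monocyte and macrophage, and 227 and 222 for neutrophils and monocytes against undifferentiated cells. Without libraries with over 50% short peaks they were 3098, 991 (297 and 694), 3853 (1047 and 2806) and 1051 for neutrophil against monocyte, monocyte-derived macrophage against monocyte and macrophage, and neutrophil against undifferentiated, and 5 for LPS. Without monocyte-derived macrophages LPS gave 5, with fewer libraries. The logistic expectation gave 2723 for neutrophil against monocyte, 252 for late neutrophils and 14 for LPS. With 50% overlap the late monocyte split was 250 and 1074.

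List shares and gene-end shares moved too. Numbers of lists called without adjustment for list length were 4, 1, 2, 0, 3, 4, 0, 2 and 0 for macrophage against neutrophil and monocyte, neutrophil against monocyte, monocyte-derived macrophage against monocyte and macrophage, late macrophages, neutrophils and monocytes, and LPS. With libraries of at least 5000 peaks they were 2 for macrophage against monocyte, 1 for monocyte-derived macrophage against monocyte and 1 for monocyte against undifferentiated. Genes within 10 kb gave 2 for macrophage against monocyte and 0 for LPS, and within 100 kb 2 for macrophage against monocyte. Wide peaks gave 1 for macrophages and 1 for monocytes against undifferentiated cells and 3 for late neutrophils, and leaving out libraries with over 50% short peaks 0 for LPS. Without adjustment for list length the difference in gene-end share was -6.106 and -1.15 points for macrophages against neutrophils and monocytes, 6.103 and 6.145 for monocyte-derived macrophages against monocytes and macrophages, 17.27 and 11.93 for neutrophils and monocytes against undifferentiated cells, and -7.035 and 4.391 for late macrophages and monocytes. With wide peaks it was -0.1029 for macrophages against neutrophils, -0.03365 and 0.06928 for macrophages and neutrophils against undifferentiated cells, and 3.261 and 11.69 for late macrophages and neutrophils (adjusted p = 0.008095 each, exact permutation test). Within 2 kb it was 0.1498 for neutrophils against undifferentiated cells and 3.586 for late macrophages (adjusted p = 0.04255, exact permutation test), and without libraries with over 50% short peaks 3.591 for late macrophages (0.02547).

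Signs turned at a few regions and lists, none of them past the threshold after the turn. With 50% overlap the difference was -0.1144 for MCM6 and -0.2128 for RNASE2 (neutrophil against monocyte), -0.06939 for TBKBP1 (monocyte-derived macrophage against monocyte) and -0.03135 for ATP8A1 (late monocytes). With wide peaks it was -0.06386 for CWH43 (monocyte-derived macrophage against macrophage), -0.01929 for ATP8A1 and -0.02359 points for the AP-1 and immediate-early share of monocyte-derived macrophages against macrophages. Shares not called in the report also turned. Without adjustment for list length, that of neutrophil granule genes was 0.000331 (macrophage against neutrophil) and that of macrophage genes -0.01029 (monocyte against undifferentiated). Genes within 10 kb gave 0.00153 for the former and -0.001868 for cell cycle genes (neutrophil against monocyte), which were at -0.002036 without libraries with over 50% short peaks.

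Leaving out each replicate number gave the following lowest and highest values. Region counts ranged from 3280 to 7372 and 2446 to 3204 for macrophage against neutrophil and monocyte, 1365 to 2839 for neutrophil against monocyte, 79 to 5903 and 1946 to 7183 for monocyte-derived macrophage against monocyte and macrophage. Against undifferentiated cells they were 290 to 1901, 0 to 313 and 0 to 8 for macrophages, neutrophils and monocytes. Late against early gave 967 to 3336, 2 to 95 and 2 to 1564 for macrophages, neutrophils and monocytes, and LPS 0 to 1. Counts of 0 came without replicate 2 and without replicate 3, with 7027 and 6325 (neutrophils), 2842 and 5061 (monocytes) and 2434 and 2188 (LPS) at an unadjusted p under 0.05 by limma. List calls ranged from 2 to 4, 0 to 2, 0 to 4, 0 to 1 and 1 to 3 for the first 5 comparisons, stayed at 0 for the 3 against undifferentiated cells, and ranged from 0 to 4, 0 to 0 and 0 to 2 for late macrophages, neutrophils and monocytes and 0 to 1 for LPS. The cell cycle share of neutrophils against monocytes ranged from -0.0112 to 0.02038. Gene-end share ranged from -0.8807 to 3.279 and 1.813 to 3.588 for macrophages against neutrophils and monocytes, -0.5643 to 3.352 for neutrophils against monocytes, -0.009889 to 1.428 and -1.851 to 0.8708 for macrophages and neutrophils against undifferentiated cells, and 3.196 to 4.18 for late monocytes. The log10 number of peaks per library ranged from -0.04567 to 0.3625 and -0.1468 to 0.03223 for macrophages and neutrophils against monocytes, -0.02187 to 0.1229 and -0.1407 to 0.352 for monocyte-derived macrophages against monocytes and macrophages, -0.1723 to 0.03365 for late monocytes and -0.1018 to 0.2112 for LPS.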

Other observations

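Tests chosen after the result was seen were those of list length, of the additive model and of short peaks as the whole cause for monocyte-derived macrophages, those of gene density and of wide peaks for chromosome 18, and the comparison of LPS-treated monocyte-derived macrophages with other groups.

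The times of detection of some named macrophage regions are given here as counts. SMIM21 and PIK3C3 were named for detection in nearly all macrophage libraries, so their presence at 3 h followed from the naming. LCP2, CD9, VDR and PPARG were named for late gains over early libraries that had none, so their early absence is no separate result. The region at SMIM21 was already detected in 3 of 3 macrophage libraries at 3 h and the one at PIK3C3 (chromosome 18, 41938271 to 41938916) in 2 of 3, and both were absent from 3 of 3 undifferentiated libraries. The regions at LCP2, CD9, VDR, PPARG and ALPL were detected in no macrophage library at 3, 6 or 12 h and, at 24 h, in 3, 2, 1, 3 and 3 of 3 macrophage libraries. This PIK3C3 region and those at RARG and MPO were also detected in monocyte-derived macrophages at 168 h, in 3, 3 and 2 of 3 libraries, but in 0 of 3 after LPS, and LCP2 and VDR in 0 of 3 with or without LPS. In neutrophils, IL1RAP was detected in 3 of 3 libraries at 24 h, 0 at 48, 96 and 120 h, and 2 of 3 after LPS at 120 h, and LYN in 0 libraries at 48, 96 and 120 h and 3 of 3 after LPS. JUND was detected in 3 of 3 undifferentiated libraries, in 0 of 3 macrophage libraries at each time from 12 to 120 h, and in 12 of 15 libraries of monocyte-derived macrophages. These are counts per group of 3 or fewer libraries and were not tested group by group.

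Regions lower at late times overlapped between lineages. Macrophages and monocytes shared 112 regions lower at late times, where independent lists of these lengths would share 27.1, and 102 higher ones (47.6 for independent lists), with 9 regions changed in opposite directions. Macrophages and neutrophils shared 61 lower regions (11.4 for independent lists) and 6 higher ones (3.54), and neutrophils and monocytes 20 lower (7.29) and 1 higher (0.283). The lineages have no libraries in common, but independent lists leave out that regions differ in how often they are detected at all, so the excess was not tested.

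The 3 LPS-treated libraries of monocyte-derived macrophages did not resemble the untreated ones. Over all tested regions, after adjustment for list length, their correlations with the mean of late monocytes were 0.14, 0.149 and 0.0955, and with that of untreated monocyte-derived macrophages -0.0402, -0.0112 and -0.0183. With undifferentiated cells they were 0.135, 0.129 and 0.00418, so in 2 of 3 libraries the likeness was not specific to monocytes. The 3 untreated libraries at 144 h had correlations of -0.0506, -0.115 and -0.155 with late monocytes and 0.14, 0.373 and 0.475 with the other times of their lineage. An effect of LPS, a different treatment and a wrong label were not tested against each other, so the LPS results of this condition are not shown to be due to LPS.

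The lower detection in monocyte-derived macrophages than in direct macrophages (9652 regions against 1788) was weighed against properties of the lists. Shorter lists cannot be told apart from equal ones: theirs were 1.143 times as long, but the range of 2 SE was 0.599 to 2.18, and without replicate 2 or 3 they were shorter (-0.1407 and -0.03739 in log10). The higher percentage of short peaks as the whole cause is argued against by 1421 regions still lower with that percentage as a covariate. As part of the cause it stays open. In 48 libraries of the other lineages, mean detection at these 9652 regions fell with the percentage of short peaks. The slope predicted a difference of -0.0791. That was 89.73% (SE 47.0) of -0.0882, which is the mean difference over all tested regions and not over those called lower. Whether the 50% written before was reached at the lower regions thus cannot be told. The same holds for a rule on the SE that was added after the value was seen. The linear treatment of list length may be behind the imbalance, since with the logistic expectation 53.3% of calls were lower, and a biological difference between the routes stays open and untested.

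Peaks were dense on chromosome 18 and at 8q24. Chromosome 18 held 2.02 times as many peaks away from gene ends per megabase as the median of the other chromosomes, and 4 windows of 1 Mb between 125000001 and 134000000 of chromosome 8 were among the 10 densest of 2921, the first with 3121 peaks against a median of 642. Extra copies in all cells of the line are a candidate explanation, as peaks were denser on chromosome 18 in 92 of 92 libraries, the undifferentiated ones included (2.03 to 2.43 times). A higher number of genes is argued against by the density near gene ends, 0.7577 times the median, and shallow calls of short peaks by the density of wide peaks, 1.807 times the median. Copy number was not measured, and none of these tests addressed 8q24 alone.

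For the 12 comparisons of regions, other splits of the same libraries were counted. Chance can be excluded for macrophages against neutrophils (11684 regions, highest of the other splits 323), macrophages against monocytes (9076, highest other 661), neutrophils against monocytes (5308, 960), monocyte-derived macrophages against monocytes (4874, 1163) and against macrophages (11440, 434). The same holds for macrophages against undifferentiated cells (8047, 4330) and late against early macrophages (7455, 3436). In each of these, 1 of 100 splits was as large, the real one, which is the lowest share that 100 splits can give. That share was also 1 of 100 for neutrophils against undifferentiated cells (1994, highest other 1865) and late against early monocytes (1474, 653). Leaving out a replicate number left 0 to 313 and 2 to 1564 calls there, so chance is not called excluded for these 2. For monocytes against undifferentiated cells (454, highest other 1302) and late against early neutrophils (457, 529) 2 of 100 splits were as large, the real one included. Another split thus exceeded the real count in both. Leaving out a replicate number left 0 to 8 and 2 to 95 calls, so chance is not excluded for these comparisons. In the former, a split with several times the real count points to a structure of the samples. Chance cannot be excluded for LPS (28, highest other 1339, 10 of 100 splits), where such a structure is also seen.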
